A study of Mus musculus with 6 samples.

How the data were processed

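The values analysed were the deposited expression values, 1 per probe set and array for 45101 probe sets and 6 arrays. Per the submitters' processing notes they had been computed with RMA, which corrects background, normalizes quantiles across arrays and summarises the probes of a set. The deposited values were intensities on a linear scale, so log2 was taken before any other step, with no pseudocount. The design had been written for log2 values. Raw array scans were not used here.

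Probe sets were matched to genes through the platform's annotation table. Of these, 35890 probe sets were listed, 34945 of them with 1 gene, 932 with several and 13 of the 64 control probe sets with none, and 9160 others that are not controls were not listed. Probe sets with 1 gene gave 18193 genes, and each gene was read by the probe set with the highest mean over all 6 arrays. Levels are given as the mean ± SD of log2 intensity with n = 2 arrays per group. Aicda, Ighd and Ccnb1 had no listed probe set and were not analysed here.

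Differences were fitted with limma (lmFit and eBayes) on all 6 arrays with the group as the only term, which left 3 residual degrees of freedom and a prior of 4.36. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes were called. SE is the moderated standard error of a log2 difference, and limma's tests are two-sided. As nothing in the labels says that the replicates came from separate animals, p-values then measure only the spread between these samples.

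33 gene lists of cell functions, B cell states and markers of other cells, with 715 genes of which 621 were measured, were tested with camera at its preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry. Some genes are in more than 1 list, so the lists are not separate pieces of evidence. The Polycomb list, for example, shares Ezh2 with the germinal centre list and Uhrf1 with the DNA replication list. Lists, groups, comparisons, thresholds and alternatives were set before the data were examined, except where the text says otherwise. The genes named are, among those called whose arrays do not overlap between the groups, the 10 with the largest change in each direction (5 for 1 zone against naive cells), passing over clone and model names, or the next by p where fewer were called. Cxcr4, Cd83, Cd86, Aicda, Bcl6, Ccnb1, Myc and Ighd were always to be named, and so were 2 to 4 members with the largest change of each list described. Pttg1, Lmo2, Ube2c and A630023P12Rik fall outside this rule and were chosen after their values were seen.

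The method was tested on simulated data, 10 sets of 18193 genes with 200 changed genes each. Between the zones limma recovered 10.5% of 2-fold and 95% of 4-fold changes, with 8.50% false among those called. Between germinal centre and naive cells it recovered 30.7% and 99.1%, with 7.75% false. The fit of the 4 zone arrays with the replicate number as a term recovered 99.8% and 100%, with 8.47% false. That fit has 1 residual degree of freedom and was chosen after seeing the data. Its recovery holds for the simulated data and does not show what share of real changes it finds. The false share in each of these fits was above the threshold set for the adjusted p. Camera called 98.3% of lists shifted by 0.5 and 0.625% of lists not shifted. The simulated genes varied independently, so these rates do not hold for lists of correlated genes. The estimated correlation was 0.15 for mitosis genes and 0.34 for NF-kB and CD40 target genes. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The version of RMA is not stated in the labels.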

Results

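RNA from 3 populations of mouse B cells was hybridised to Affymetrix expression arrays, with 2 arrays per population and 6 arrays in all. Germinal centres are sites in lymphoid organs where B cells responding to an antigen divide, mutate their antigen receptor genes and are selected. They are split into a dark zone and a light zone. The germinal centre cells here were transferred B cells that carried a high-affinity hapten receptor (B1-8hi) and a photoactivatable green fluorescent protein. Light switched this protein on in 1 zone of the lymph nodes at day 7, and the cells that glowed were then sorted as light zone or dark zone cells. The naive cells were IgD+ CD19+ B cells sorted from spleen. The levels below are log2 of the deposited intensities for 18193 genes, each read by its brightest probe set. Array medians were between 20.998 and 23.7 on the linear scale, and upper quartiles were 60.6 in naive replicate 2 and 80.7 to 91.9 in the other 5 arrays. The labels call the arrays of a group biological replicates, and the number of arrays, 2 per group, limits the precision of every value.

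The arrays also differed in a way the groups do not explain. Bacterial control probe sets (BioB) had mean intensities of 2268 (light zone), 2257 (dark zone) and 3041 (naive) on the arrays numbered 1. On the arrays numbered 2 they were at 620, 410 and 553. Zone differences are therefore also given within each number as the difference in the replicates numbered 1 and in those numbered 2. The replicates of the naive group were farthest apart, with an SD of the replicate difference of 0.71 across genes, against 0.39 in the light zone and 0.36 in the dark zone.

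The comparison of light zone with dark zone cells asked which genes the cells express differently in each compartment. Genes of mitosis, which build the spindle and part the chromosomes, were lower in the light zone, with a median difference over 33 genes of -0.998 (log2, light zone minus dark zone; camera adjusted p = 1.15e-56, adjusted p = 0.0758 with an estimated correlation). All 33 were lower in both replicate numbers, where the medians were -1.07 and -0.88. Limma called 26 of them, all lower, adjusted over the list alone. Ccnb2, a B-type cyclin that drives entry into mitosis, was 3.44-fold higher in the dark zone (difference -1.78, SE 0.28, n = 2 arrays per zone, limma adjusted p = 0.471). Cdc20, which directs the destruction of mitotic proteins, differed by -1.60 (SE 0.32), at 9.72 ± 0.10 in the light zone and 11.32 ± 0.25 in the dark zone (log2 mean ± SD, n = 2). Variant histone genes fell with them, with a median of -0.70 over 4 genes (camera adjusted p = 7.13e-06, adjusted p = 0.181 with an estimated correlation), and H2ax, which marks DNA breaks, differed by -0.80. Genes of DNA replication did not move as a list, with a median of -0.02 (camera adjusted p = 0.658), nor did cyclins and cell cycle entry genes, with a median of -0.03 (camera adjusted p = 0.917).

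**Figure D1:**
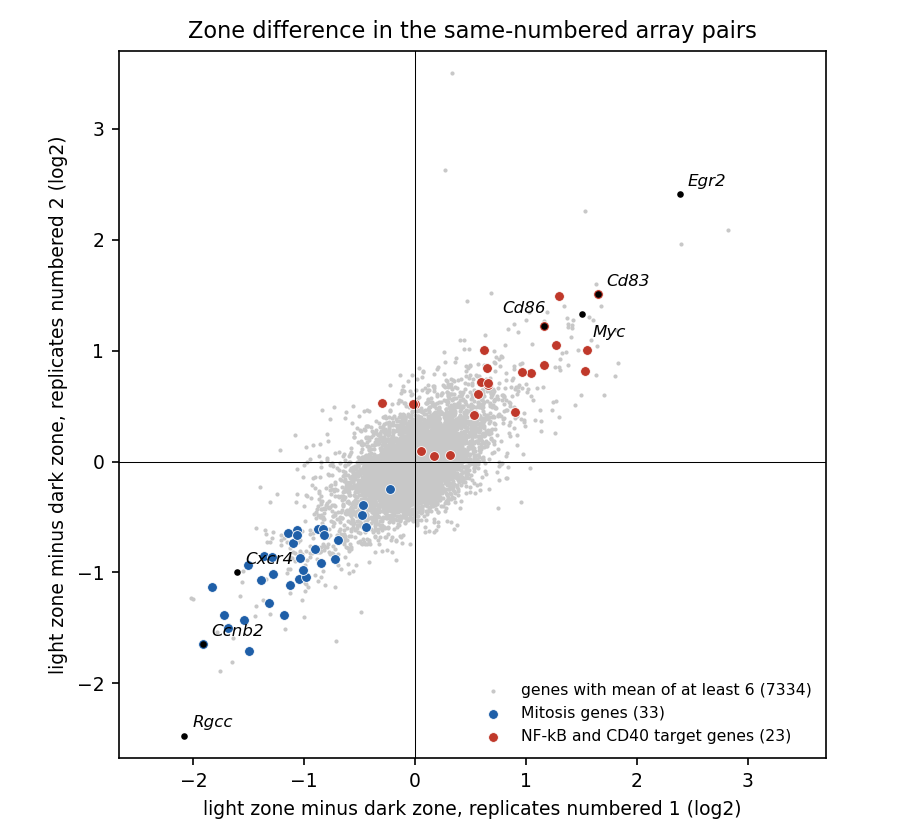
Light zone minus dark zone (log2) in the replicates numbered 2 against the same difference in the replicates numbered 1, one point per gene for 7334 genes with a mean level of at least 6, plus Rgcc and Ccl22, with mitosis genes in blue and NF-kB and CD40 target genes in red. All 33 mitosis genes lie below 0 on both axes, and 20 of the 23 NF-kB and CD40 target genes lie above 0 on both.

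Genes driven by NF-kB and the costimulatory receptor CD40 showed the opposite pattern and rose in the light zone, with a median of 0.68 over 23 genes (camera adjusted p = 7.43e-23, adjusted p = 0.202 with an estimated correlation). Of these, 20 were higher in both replicate numbers (medians 0.65 and 0.72). Limma called 9 adjusted over the list alone, all higher. The transcription factor Irf4 was higher by 1.40 and Cd83, a surface protein of activated B cells, by 1.58. Early response genes, which are switched on within minutes to hours of antigen receptor engagement, rose by a median of 0.31 over 27 genes (camera adjusted p = 7.79e-13, adjusted p = 0.196 with an estimated correlation), with 5 called by limma adjusted over the list alone and a median of 0.50 without light zone replicate 1. The zinc finger transcription factors Egr2 and Egr1 were higher by 2.40 and 2.18, and Egr3 by 2.46 with an SE of 0.86, or by 1.34 without dark zone replicate 1. Egr2 was at 8.29 ± 0.29 in the light zone, 5.89 ± 0.27 in the dark zone and 5.57 ± 0.80 in naive cells (log2 mean ± SD, n = 2). Myc, a transcription factor for cell growth, was 2.67-fold higher in the light zone (difference 1.42, SE 0.29, n = 2, limma adjusted p = 0.696, probe set 1424942_a_at). Genes that MYC activates for ribosome building rose as a list by 0.38 over 26 genes (camera adjusted p = 7.79e-13, adjusted p = 0.0758 with an estimated correlation), with 25 higher in both replicate numbers. Adjusted over the list alone, limma called 0 of them, with 3 at an unadjusted p under 0.05. The nucleolar GTPase Gnl3 was higher by 1.12 and the polyamine enzyme Srm by 1.06.

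Lists of metabolism and cell fate also moved. Some share members with the list of NF-kB and CD40 targets, such as Slamf1 (T cell help), Irf4 (plasma cell) and Cflar (apoptosis). Sterol and fatty acid synthesis genes rose in the light zone by a median of 0.59 over 20 genes (camera adjusted p = 3.61e-11, adjusted p = 0.376 with an estimated correlation), with medians of 0.85 and 0.29 in the replicate numbers and Cyp51, a lanosterol demethylase, at 0.98. Glycolysis genes rose by 0.17 (camera adjusted p = 0.000515, adjusted p = 0.376 with an estimated correlation), led by Aldoc at 1.13 and hexokinase 2 (Hk2) at 0.84. Oxidative phosphorylation genes fell by a median of 0.14 (camera adjusted p = 0.0191, adjusted p = 0.729 with an estimated correlation), with medians of 0.01 and -0.24 in the replicate numbers. Plasma cell and secretory genes rose by 0.27 over 22 genes (camera adjusted p = 4.38e-06, adjusted p = 0.202 with an estimated correlation), including Prdm1, the repressor that drives plasma cell fate, at 1.71 (SE 0.43), or 0.99 without light zone replicate 2, from a dark zone level of 4.03, near background. Antigen presentation genes rose by 0.27 over 18 genes (camera adjusted p = 0.000198, adjusted p = 0.451 with an estimated correlation). Among them Ifi30, a lysosomal thiol reductase that opens antigens for loading, was higher by 1.26, and Ciita, which switches on MHC class II genes, was higher by 0.68. Genes for receptors and ligands of T cell help had a median of 0.07 and a mean of 0.20 over 20 genes (camera adjusted p = 0.00506, adjusted p = 0.271 with an estimated correlation), with Slamf1, an adhesion receptor of T and B cells, at 1.16. Naive follicular B cell genes rose by 0.22 (camera adjusted p = 0.00801, adjusted p = 0.603 with an estimated correlation), among them Gpr183, an oxysterol receptor that guides B cells in follicles, at 1.35 and the IgE receptor Fcer2a at 1.05. Marginal zone and B1 marker genes had a median of 0.06 and a mean of 0.33 (camera adjusted p = 0.00460, adjusted p = 0.202 with an estimated correlation). Apoptosis regulators had a median of 0.06 (camera adjusted p = 0.0257, adjusted p = 0.527 with an estimated correlation), with the survival genes Bcl2 and Cflar at 0.89 and 0.75. Camera did not call this list with the 4 zone arrays and the replicate number as a term (adjusted p = 0.0720). Germinal centre B cell genes fell in the light zone by a median of 0.28 over 16 genes (camera adjusted p = 0.00801, adjusted p = 0.216 with an estimated correlation), with Gcsam at -1.49. Several of these medians moved over 1.5 times, or lost camera's call, when 1 array was left out. Without light zone replicate 1 they were -0.12 for germinal centre, 0.40 for naive follicular, 0.32 for T cell help, 0.25 for apoptosis and 0.12 for marginal zone genes. Without light zone replicate 2 camera no longer called marginal zone (0.24), oxidative phosphorylation (-0.07) and apoptosis genes (0.07), and the medians were 0.16 for antigen presentation, 0.13 for plasma cell, -3.58e-05 for naive follicular and -0.03 for T cell help genes. Without dark zone replicate 1 it no longer called glycolysis (0.20), T cell help (0.06) and germinal centre genes (-0.23), and the medians were 0.17 for antigen presentation, 0.17 for plasma cell, 0.27 for marginal zone and -0.06 for apoptosis genes. Without dark zone replicate 2 it no longer called oxidative phosphorylation genes (-0.02), and the medians were 0.33 for naive follicular, 0.12 for T cell help, 0.48 for plasma cell, 0.19 for apoptosis and 0.27 for glycolysis genes.

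**Figure D2:**
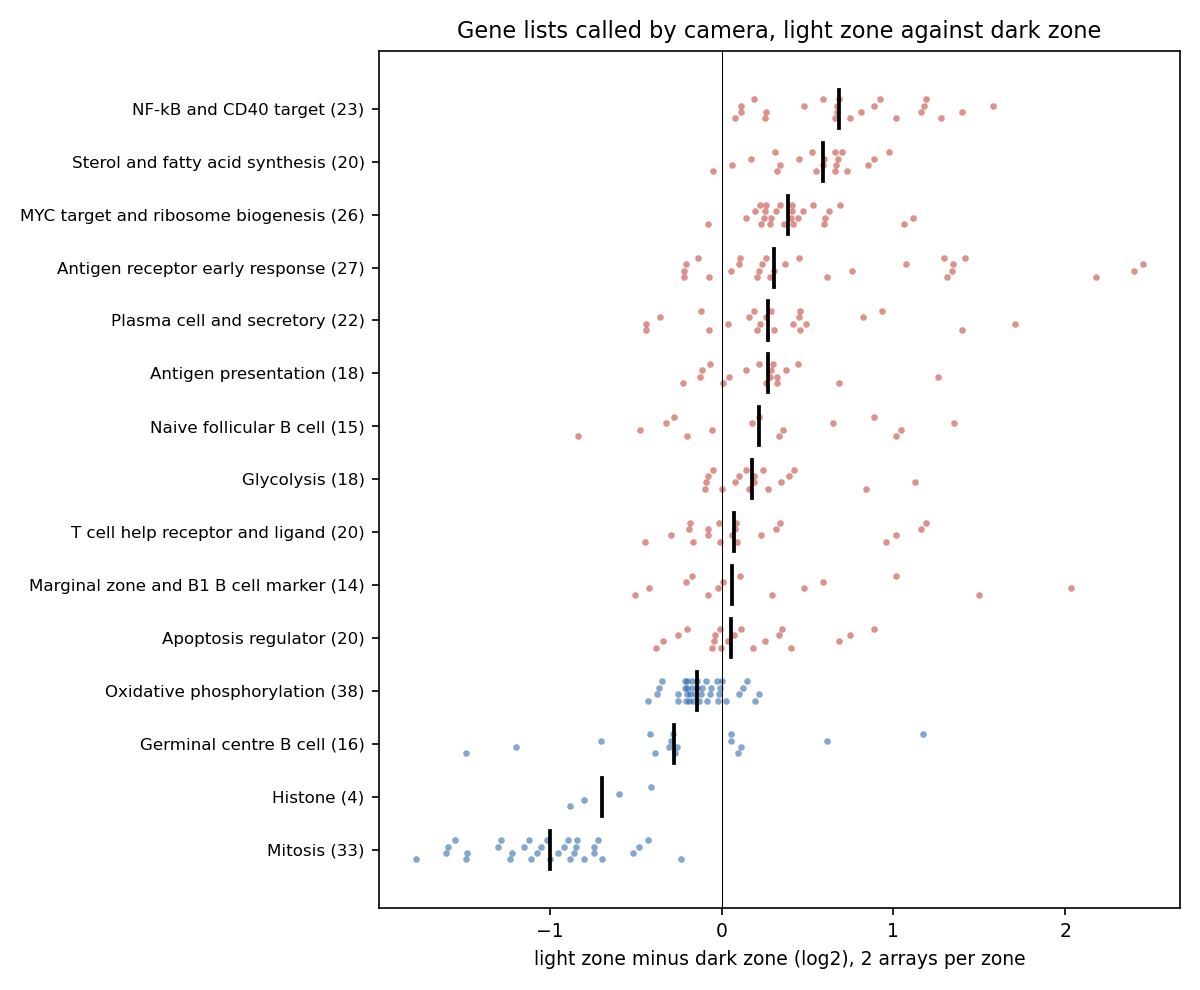
Light zone minus dark zone (log2, x axis) for each measured gene (dots) of the gene lists on the y axis, with the list median as a black bar, and lists called higher by camera in red, lower in blue. The mitosis list has a median of -0.998 and the NF-kB and CD40 target list a median of 0.68.

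Single genes with the clearest zone difference included regulators of signalling and movement. Rgcc, a regulator of cell cycle kinases, was 4.85-fold higher in the dark zone (difference -2.28, SE 0.26, n = 2, limma adjusted p = 0.412), and Gcsam, a germinal centre adaptor that restrains B cell movement, 2.81-fold higher (difference -1.49, SE 0.21, n = 2, limma adjusted p = 0.413). Other genes ranked lower in the light zone were Pif1 (-1.86), a DNA helicase, Psrc1 (-1.82), which binds spindle microtubules, Otub2 (-1.82), Pafah1b3 (-1.73), Tifa (-1.66), the phosphatase Cdkn3 (-1.62) and Ptgr1 (-1.34). Ranked higher, beside Cd83 and the Egr genes, were the lipid scramblase Plscr1 (2.03), the leukaemia inhibitory factor receptor Lifr (1.85), the GTPase Gimap4 (1.37), Snn (1.31) and the protease inhibitor Slpi (1.27). Cd83 (probe set 1416111_at) was at 12.39 ± 0.11 in the light zone, 10.81 ± 0.21 in the dark zone and 11.40 ± 0.25 in naive cells (SD, n = 2), and its difference of 1.58 had an SE of 0.24. The costimulatory ligand Cd86 (1420404_at) was at 10.06 ± 0.09 in the light zone and 8.86 ± 0.05 in the dark zone, with differences of 1.16 and 1.22 in the replicate numbers. Cxcr4 (1448710_at), the chemokine receptor that draws cells into the dark zone, was at 9.02 ± 0.67 in the light zone and 10.33 ± 0.24 in the dark zone, with differences of -1.61 and -1.0. The cells were sorted by photoactivation and not by these 3 genes, which had been named in advance as known markers of the zones, and without light zone replicate 1 the difference of Cxcr4 was -0.83. Bcl6 (1421818_at), the repressor that germinal centre B cells require, did not differ beyond its error, at 10.82 ± 0.09 and 10.77 ± 0.13 (difference 0.05, SE 0.35).

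**Figure D3:**
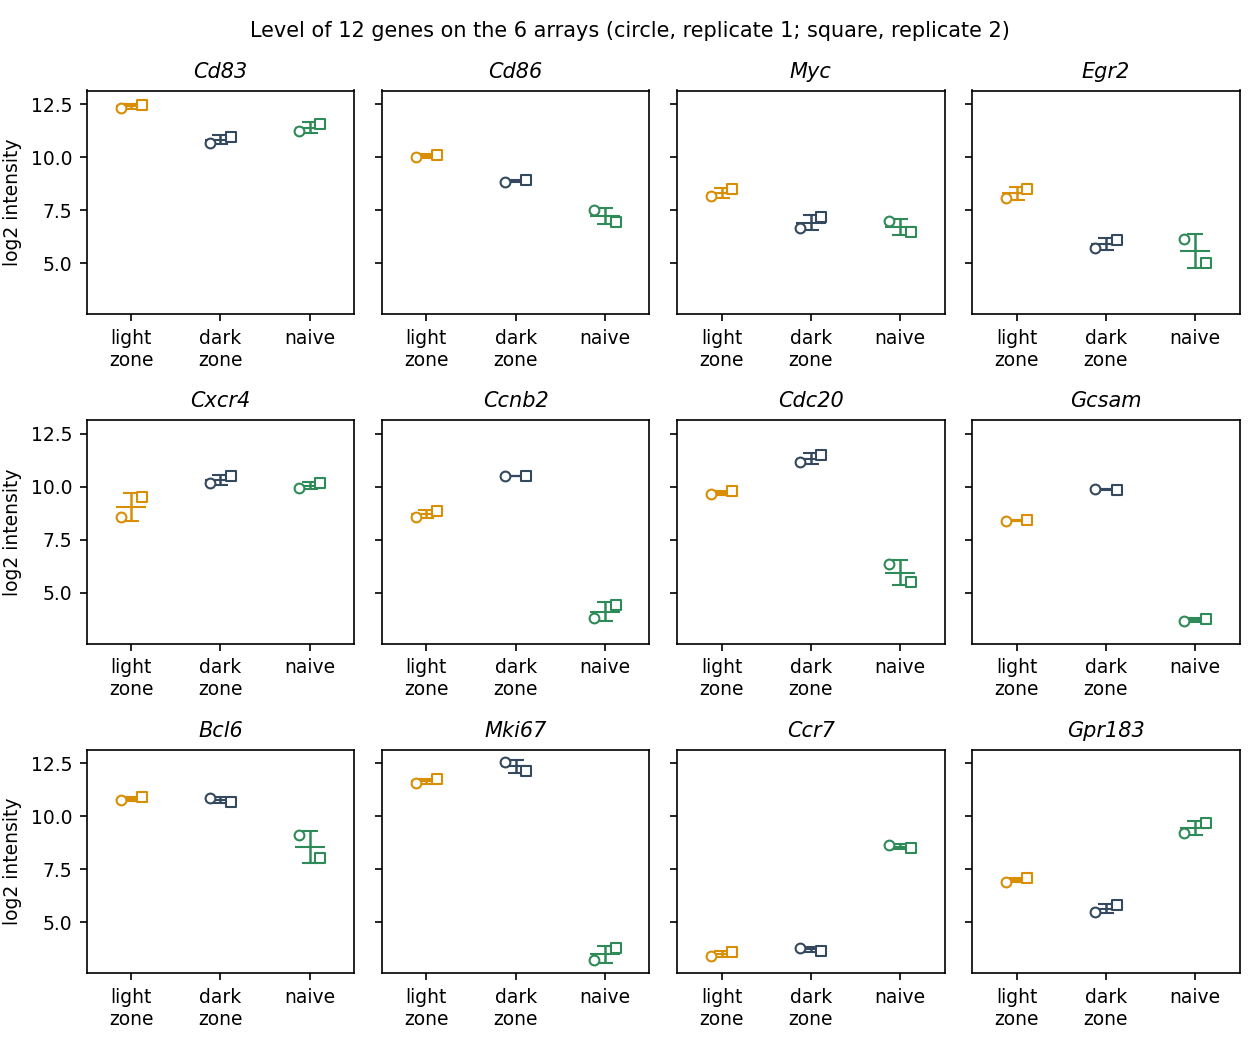
Level (log2 intensity, y axis) of 12 genes in light zone, dark zone and naive B cells (x axis), with a circle for the replicate numbered 1, a square for the replicate numbered 2 and bars for the mean ± SD. Cd83 averages 12.39 in the light zone and 10.81 in the dark zone, and Ccnb2 averages 8.71 and 10.50.

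Gene by gene with all 6 arrays in the fit, limma called 0 of 18193 genes between the zones, with 423 at an unadjusted p under 0.05 and a smallest adjusted p of 0.412. The naive arrays, whose replicates were farthest apart, enter the spread of that fit. The median SE was 0.268 there, 0.195 with only the 4 zone arrays and 0.150 with the replicate number as a term as well. With only the 4 zone arrays in the fit limma called 14, of which Egr1, Egr2 and Socs3 were higher in the light zone and A630023P12Rik, Ccnb2, Cdkn3, Gcsam, Otub2, Pafah1b3, Pif1, Psrc1, Rgcc, Tifa and Ube2c were lower. A630023P12Rik and Ube2c were singled out after their values were seen. Leaving out 1 naive array gives the same zone fit and is no further check, since a group of 1 array adds nothing to the spread. Arrays weighted by their quality gave 38 calls. A fit of the 4 zone arrays with the replicate number as a term, chosen after seeing the data, called 405 genes, 173 higher and 232 lower in the light zone, of which 144 differed at least 2-fold. It has 1 residual degree of freedom. In that fit limma called 29 mitosis genes lower and 13 NF-kB and CD40 target genes higher, and gave adjusted p = 0.000549 for Cd83, 0.00109 for Myc, 0.00231 for Cd86 and 0.00365 for Cxcr4. The labels do not say that numbers pair the arrays. Across genes, though, the replicate difference of the light zone went with that of the dark zone (r = 0.57). With that of naive cells r was -0.09 for the light zone and -0.05 for the dark zone. A fit without the replicate term leaves what the zones share by number in the spread. At least 2-fold in both replicate numbers, 36 genes were higher in the light zone, 54 were lower and 0 went opposite ways. Across genes the 2 within-number differences had r = 0.41, and 0.65 over the 7334 genes with a mean level of at least 6, though genes are not independent replicates. Camera called 15 lists with its preset correlation and 0 with an estimated one. Fry called 2, mitosis and histone genes. The 3'/5' signal ratio of actin was 3.35 in the light zone and 2.76 in the dark zone for number 1 and 1.62 and 1.52 for number 2, so a sign of RNA quality moved with the zones.

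The comparison of germinal centre with naive B cells asked what sets responding cells of either zone apart from resting ones, with the mean of both zones set against naive cells. By camera at its preset correlation the clearest difference was proliferation, while fry and an estimated correlation ranked the germinal centre B cell list first. Mitosis genes rose by a median of 4.58 (log2, germinal centre minus naive; camera adjusted p = 3.58e-42, adjusted p = 0.0775 with an estimated correlation), and limma called 32 of 33 higher and 1, Pttg1 (-0.88), lower. DNA replication genes rose by 2.62 (camera adjusted p = 1.13e-32, adjusted p = 0.0775 with an estimated correlation), with 31 of 34 called by limma, or 32 adjusted over the list alone. Mki67, a protein of dividing cells that coats their chromosomes, rose by 8.53 (SE 0.25, n = 4 arrays against 2, limma adjusted p = 1.31e-05), at 11.65 ± 0.12 in the light zone, 12.35 ± 0.31 in the dark zone and 3.47 ± 0.41 in naive cells. Rrm2, a subunit of the enzyme that makes DNA precursors, rose by 7.92, the replication clamp partner Pclaf by 7.32, the survivin gene Birc5 by 6.50, Cep55 by 6.41, Top2a by 6.29 and Mybl1 by 6.26. In naive cells Mki67, Rrm2, Birc5 and Cep55 were at 3.47, 3.33, 3.37 and 3.57, near the lower quartile of the arrays (9.88 to 12.2 on the linear scale), so the size of such differences depends on the background signal and no fold is given. The kinetochore genes Nuf2 and Bub1 rose by 5.89 and 5.58, and Cdc6 and Uhrf1 by 4.76 and 4.87. Cyclins and cell cycle entry genes rose by 0.89 (camera adjusted p = 0.00982, adjusted p = 0.623 with an estimated correlation), or 0.35 without naive replicate 1, with Ccne2 at 4.91, E2f3 at 1.89 and Ccnd3 at 2.18, although 1 probe set of Ccnd3 went the opposite way and the list's call was lost after quantile normalization was applied again (0.51, camera adjusted p = 0.0538), while the cell cycle inhibitor Cdkn1b fell (-2.98). Histone genes rose by 1.23 (camera adjusted p = 0.0181, adjusted p = 0.323 with an estimated correlation), with H2ax at 3.50, a call lost without naive replicate 1 (1.28).

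Genes that mark each cell state went opposite ways. Germinal centre B cell genes rose by a median of 3.97 (camera adjusted p = 1.69e-21, adjusted p = 0.0634 with an estimated correlation), and limma called 15 of 16 higher and only Lmo2 (-1.19) lower. Bcl6 was 4.74-fold higher (difference 2.24, SE 0.31, limma adjusted p = 0.00383), Rgs13, which damps chemokine signals, rose by 5.57, S1pr2, which holds cells in the germinal centre, by 4.05 and the death receptor Fas by 3.74. Eaf2, an elongation factor partner, rose by 6.71, Rassf6 by 6.38 and the membrane protein Basp1 by 5.91. Jchain, which joins secreted antibody units, rose by 8.70 (SE 0.36, limma adjusted p = 2.26e-05) from a naive level of 3.62 ± 0.96, near background. Genes of hypermutation and class switch repair rose by 1.75 (camera adjusted p = 6.08e-13, adjusted p = 0.267 with an estimated correlation), with 14 of 21 called higher, among them the glycosylase Neil1 at 4.72, the exonuclease Exo1 at 4.08, Brca1 at 3.74 and the mismatch repair gene Msh6 at 2.70. Naive follicular B cell genes fell (-2.22; camera adjusted p = 1.28e-09, adjusted p = 0.323 with an estimated correlation), with 11 of 15 called lower by limma and a median of -1.38 without naive replicate 1. Ccr7, a chemokine receptor for T cell areas, was lower in germinal centre cells (difference -4.95, SE 0.19, limma adjusted p = 2.03e-05), where it was near background at 3.50 and 3.70, and Klf2, Bcl2 and Gpr183 fell as well (-3.41, -3.34 and -3.14). Other large decreases were those of S100a10 (-5.53), the actin binding gene Cnn3 (-5.47), Plac8 (-5.18), the protease inhibitor Serpinb1a (-4.63), Ly6d (-4.22) and the complement regulator Cd55 (-4.13).

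Among the 10 genes with the largest decreases, 3 were antibody variable genes. Ighv14-2, a heavy chain variable gene, was 61.1-fold lower in germinal centre cells (difference -5.93, SE 0.34, limma adjusted p = 6.83e-05), and the kappa light chain variable genes Igkv9-120 and Igkv6-14 differed by -4.68 and -4.19, with Igkv9-120 near background in germinal centre cells (3.83 and 4.01). The kappa locus gene Igk fell by 1.88 while the lambda gene Iglv1 rose by 1.83, although 1 of the 3 probe sets of Iglv1 went the opposite way and the mean of its probe sets gave -0.11. Its call was lost without light zone replicate 1 (1.88), light zone replicate 2 (1.77), dark zone replicate 1 (1.88) or dark zone replicate 2 (1.77). The labels give the B1-8hi receptor for the transferred cells and no single receptor for the naive cells. As a list the 5 immunoglobulin genes did not move (camera adjusted p = 0.724).

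Some lists of metabolism and chromatin rose in germinal centre cells. Oxidative phosphorylation genes did not pass (median 0.03, camera adjusted p = 0.248). Sterol and fatty acid synthesis genes rose by 1.24 (camera adjusted p = 1.18e-06, adjusted p = 0.623 with an estimated correlation), with Sqle, the squalene epoxidase, at 3.11, Idi1 at 2.75 and Hmgcs1 at 2.55. Their medians in the replicate numbers were 0.68 and 1.51, and 0.64 was left without naive replicate 2. MYC target and ribosome biogenesis genes rose by 0.62 (camera adjusted p = 1.29e-05, adjusted p = 0.119 with an estimated correlation), with 4 of 26 called by limma and Nop58, a nucleolar protein that modifies ribosomal RNA, at 1.41, and the median was 0.40 without naive replicate 2. Glycolysis genes rose by 0.39 (camera adjusted p = 0.0351, adjusted p = 0.623 with an estimated correlation), led by the lactate transporter Slc16a1 at 2.45 and Pfkp at 2.17, and the median was 0.22 without light zone replicate 2 and 0.63 without dark zone replicate 1. That call was lost without dark zone replicate 2 (0.09), naive replicate 1 (0.27) or naive replicate 2 (0.36), and after quantile normalization was applied again (0.13, camera adjusted p = 0.127). Polycomb and epigenetic regulators rose by 0.63 (camera adjusted p = 0.000229, adjusted p = 0.623 with an estimated correlation), with the chromatin remodeller Hells at 4.56 and the histone methyltransferase Ezh2 at 3.89, but their medians in the replicate numbers were 0.23 and 0.81, and 0.23 was left without naive replicate 2. Interferon response genes fell (-1.18; camera adjusted p = 2.03e-05, adjusted p = 0.623 with an estimated correlation), with 8 of 23 called lower by limma, among them Rtp4 (-4.02), a receptor chaperone that interferon induces, and Xaf1 (-2.31). Their medians in the replicate numbers were -2.09 and -0.32, and the naive replicates differed by 1.10 over this list. Without naive replicate 1 the median was -0.51 and camera did not call it, while without naive replicate 2 it was -1.79. Antigen presentation genes fell (-0.36; camera adjusted p = 0.0296, adjusted p = 0.646 with an estimated correlation), with the lysosomal protease Ctss (-1.37) called lower. Without naive replicate 1 that median was -0.07 and not called, and without naive replicate 2 it was -0.59.

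In all, limma called 2129 of 18193 genes between germinal centre and naive cells, 1505 higher and 624 lower, of which 1730 differed at least 2-fold. The split depends on scaling. After quantile normalization was applied again to the deposited values, limma called 2141 genes, 1137 higher and 1004 lower, with 1691 genes shared. Centring each array on its median moved the median difference of all genes from -0.12 to -0.01 and gave 1650 higher and 445 lower. Removing 1 array moved the count by over 1.5 times for 5 of the 6 arrays. Each such fit left 1 array in a group, so the other groups alone gave the spread, and these counts are not read as results. Without 1 naive array the largest spread, that between the naive replicates, dropped out. Arrays weighted by their quality gave 1228. Within the replicate numbers, 916 genes were at least 2-fold higher in both, 323 lower in both and 41 opposite, with r = 0.63 across genes. Camera called 13 lists with its preset correlation and 0 with an estimated one, although the estimate for germinal centre B cell genes (0.0017) was under the preset of 0.01. Fry, which does not compare a list with other genes, called 13, among them macrophage and erythroid markers as lower. Of the macrophage markers limma called 3 higher and 1 lower. The naive cells came from spleen and the germinal centre cells from lymph node, so organ and cell state cannot be told apart. Signs of RNA quality moved with this comparison too, since the actin 3'/5' ratio was 5.07 and 2.30 in the naive arrays against 3.35 and 1.62 in the light zone and 2.76 and 1.52 in the dark zone, and the 18S signal was 2528 and 3657 against 311 to 1169.

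Each zone was also set against naive cells to ask whether the responding state is shared. Mki67 rose by 8.18 in the light zone and 8.88 in the dark zone over naive cells, Jchain by 8.48 and 8.92, and Rrm2 by 7.99 and 7.85. Decreases were shared too, with Ighv14-2 at -5.88 and -5.99, S100a10 at -5.33 and -5.73 and Ccr7 at -5.05 and -4.85. Mitosis genes rose by a median of 4.01 in the light zone (camera adjusted p = 1.55e-42, adjusted p = 0.0637 with an estimated correlation) and 5.07 in the dark zone (camera adjusted p = 2.81e-47, adjusted p = 0.0661 with an estimated correlation). Bcl6 rose by 2.27 and 2.22 (limma adjusted p = 0.00962 and 0.00945), and Cd86 by 2.85 and 1.66. Myc passed limma's threshold against naive cells in the light zone (difference 1.60, SE 0.29, adjusted p = 0.0189) and not in the dark zone (0.18, SE 0.29, adjusted p = 0.730). Between the zones themselves Myc did not pass with all 6 arrays (limma adjusted p = 0.696). It passed in the zone fit with the replicate number as a term (limma adjusted p = 0.00109), which was chosen after seeing the data. In the light zone the calls of Bcl6 and Myc were lost without light zone replicate 1 (2.33 and 1.76) or light zone replicate 2 (2.21 and 1.44). In the dark zone those of Bcl6 and Cd86 were lost without dark zone replicate 1 (2.13 and 1.69) or dark zone replicate 2 (2.31 and 1.62). Cxcr4 and Cd83 did not pass limma's threshold in either zone with all arrays, at -1.01 and 0.29 for Cxcr4 and 0.99 and -0.59 for Cd83. In the light zone Cd83 differed by 0.82 without naive replicate 1 and 1.17 without naive replicate 2, and in the dark zone by -0.76 without naive replicate 1. With 1 naive array left the zones alone give the spread, so no call is given for these.

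Against naive cells limma called 1335 genes in the light zone, 985 higher and 350 lower, and 1542 in the dark zone, 1137 higher and 405 lower. After quantile normalization was applied again it called 794 higher and 605 lower in the light zone, and 892 and 705 in the dark zone. With the deposited scaling both lists held 860 genes higher and 273 lower, 1133 in all, and 0 in opposite directions. Independent lists would share 61.6 and 7.79. The lists share the naive arrays, so they are not independent. Simulated data with no difference between groups gave at most 3 shared genes in 50 runs. Such data give few calls to share, so that number cannot show how much overlap the shared arrays add here. Counts depended on single arrays. Leaving out 1 array left 1 in its group, so the other groups alone gave the spread, and counts from such fits are not read as results. Without 1 naive array the largest spread, that between the naive replicates, dropped out.

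The level in naive cells of genes that separate the zones was compared last. Gpr183 was highest in naive cells, at 9.45 ± 0.32, followed by 6.99 ± 0.11 in the light zone and 5.63 ± 0.21 in the dark zone (SD, n = 2). Snn, Gimap4 and Bcl2 had the same order, with Bcl2 at 8.22, 5.32 and 4.44. Slpi and Cd86 were lowest in naive cells, with Cd86 at 7.21 ± 0.39. Tifa was as high in naive cells as in the dark zone, at 6.96 and 7.18, against 5.52 in the light zone. Genes of the dark zone were mostly low in naive cells, with Ccnb2 at 4.10 ± 0.46 and Gcsam at 3.71 ± 0.08. As limma called 0 zone genes with all 6 arrays (423 at an unadjusted p under 0.05), no planned list could be followed to naive cells. Of the 173 genes higher in the light zone in the zone fit with the replicate number as a term, which was chosen after seeing the data, limma called 43 higher and 13 lower in the light zone than in naive cells, and 19 higher and 41 lower in the dark zone than in naive cells. Of the 232 higher in the dark zone, it called 108 higher and 9 lower in the light zone and 163 higher and 3 lower in the dark zone. The zone arrays enter both steps, so these counts have no simple no-change value. The naive level minus the zone mean had a median of -0.12 over the 173 genes and -1.74 over the 232.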

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

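Of the tests in this part, those of a batch shared with the naive arrays, of the 3'/5' signal and of 1 array out of 4 were chosen after the result was seen, and the other tests were planned before.

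Probe sets that name no single gene were left out of the comparisons of genes. In a fit of all probe sets but the controls, limma called 172 of 10092 such probe sets higher in germinal centre than in naive cells and 102 lower. This is a smaller share than among all probe sets of that fit, of which it called 2678. Probe set 1442544_at was higher by 9.43 (log2, SE 0.38) and 1420577_at by 7.47, while 1419480_at and 1419481_at differed by -6.27 and -5.83. They are given because the comparisons of genes do not hold these probe sets, and naive cells serve as the control.

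The first pattern weighed is the distance between the naive replicates, where 2622 genes were at least 2-fold apart, 1669 higher in replicate 1 and 953 in replicate 2, against 237 in the light zone and 183 in the dark zone. After quantile normalization was applied again the balance turned over, with 1121 higher in replicate 1 and 1638 in replicate 2. A hybridisation batch shared by all groups would move these genes between the zone replicates too, but there their median shift was -0.0454 times that in the naive arrays. A scale left uneven by normalization was present, with upper quartiles of 80.7 in naive replicate 1 and 60.6 in replicate 2, and the balance of directions depended on it. It is argued against only as the sole source of the distance, since 72.4% of these genes stayed at least 2-fold apart after that step. Loss of 5' signal in replicate 2 would give it the higher actin 3'/5' ratio, but its ratio was 0.454 times that of replicate 1 (2.30 against 5.07). Naive replicate 2 was the farther from the zone arrays, with 3710 to 4390 genes at least 2-fold apart from each, against 2055 to 2517 for replicate 1. The actin ratio was higher in replicate 1, but the 18S signal was higher in replicate 2 (3657 against 2528). What stays open, untested, is poorer RNA in 1 of the naive arrays, a handling step of 1 array, or a difference between the mice or cells sampled.

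The second pattern is the opposite movement of mitosis genes and of NF-kB and CD40 target genes between the zones. Cells of another type in the light zone would raise all their abundant transcripts, but over the 4 lists tested (T cell, stromal, macrophage and dendritic cell markers) the highest median in either replicate number was 0.108, and 1 of 73 markers, Fscn1 (1.42 and 1.23), was at least 2-fold higher in both. Abundant markers went both ways, with Apoe at -0.28 and 0.09 and Flt3 at -0.51 and -0.50, but Lat at 0.88 and 0.74, Lyz1 at 0.44 and 0.51 and Sirpa at 0.58 and 0.12. Zap70, Lat and Cd4, the brightest of the T cell list, averaged only 6.58, 6.35 and 5.70 in the zones. A list median therefore cannot exclude a small share of such cells. A pattern carried by 1 array out of 4 would be seen in 1 replicate number alone, but the smallest median of these 2 lists in their direction was 0.655. A trend with intensity was tested with random lists matched on the mean level over all 6 arrays, of which 0 of 10000 had a median as extreme. NF-kB and CD40 targets lay near their naive level (median difference -0.33), and for them this argues against such a trend. Mitosis genes lay higher in the zones than in naive cells by a median of 4.58. Their random lists were thus not matched for level in the zones, and the test cannot decide for them. The 3'/5' ratio of actin was higher in the light zone in both replicate numbers (3.35 against 2.76 and 1.62 against 1.52) and was not tested as an explanation. It stays open beside a biological difference between the zones and, for mitosis genes, a trend with intensity.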

How the results depend on the processing

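Of the tests in this part, those of the zone arrays with the replicate number as a term, with and without quantile normalization of those arrays, were chosen after seeing the data.

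Between the zones limma called 0 genes with all 6 arrays (423 at an unadjusted p under 0.05), 14 with only the groups compared, 38 with array weights, 405 with the zone arrays and the replicate number as a term, and 680 with these arrays quantile normalized as well. Leaving out 1 array gave 0 to 14. Between germinal centre and naive cells 1228 genes were called with array weights and 975 to 6786 when 1 array was left out. With only the groups compared, limma called 757 genes between light zone and naive and 918 between dark zone and naive cells, and leaving out 1 array gave 400 to 5788 and 496 to 5939. The number shared by both lists was 383 to 4921 when 1 array was left out. Zone genes that were also called in either zone against naive cells numbered 0 to 14 when 1 array was left out, and 256 of the 405 with the replicate number as a term. Fewer arrays or degrees of freedom explain part of these moves, and the cause was not tested for the rest. Each fit without 1 array left 1 array in a group, so the other groups alone gave the spread. The ranges from such fits are therefore not read as ranges of the result. In each comparison with naive cells the highest count came without naive replicate 1, where the spread between the naive replicates dropped out. A replicate block over all 6 arrays, a check since the labels do not say that numbers pair the arrays, gave 0 calls between the zones and 1892 against naive cells. Such a block takes 1 replicate difference for all groups. Across genes that difference had r = 0.57 between the zones, but -0.09 and -0.05 between the light and dark zone and naive cells.

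With an estimated correlation camera called 0 lists between the zones and 0 against naive cells, and fry called 2 between the zones. Of 407 values of list medians 336 kept direction and call, 67 lost the call and 4 reversed. Leaving out 1 array took the zone median from -3.58e-05 to 0.40 for naive follicular genes and from -0.0328 to 0.317 for T cell help genes (both lowest without light zone replicate 2) and from -0.0561 (without dark zone replicate 1) to 0.254 for apoptosis genes, and it was -0.0796 for marginal zone and B1 genes with the dimmest 40% of genes left out. The cause was not tested.

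Of 2343 values of named genes 2142 kept direction and call, 102 lost the call, 90 gained one and 9 reversed. Bcl6 between the zones went from -0.0364 without dark zone replicate 2 to 0.144 without dark zone replicate 1, with -0.01 without light zone replicate 2, and was -0.10 with the mean of its probe sets. Myc between dark zone and naive cells went from -0.0822 without naive replicate 2 to 0.448 without naive replicate 1, with -0.07 without dark zone replicate 2, and was -0.21 after quantile normalization was applied again. Lyz2 between the zones went from -1.26 without dark zone replicate 1 to 2.35 without dark zone replicate 2, with -1.24 without light zone replicate 2. Iglv1 between germinal centre and naive cells was -0.11 with the mean of its probe sets. The cause was not tested. The median SE between the zones was 0.268 with all 6 arrays.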

Other observations

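Of the tests in this part, the correlation without the genes of the cell cycle lists alone was chosen after the result was seen. Migration and adhesion genes were divided rather than shifted. Between germinal centre and naive cells limma called 9 of 32 higher and 12 lower (camera adjusted p = 0.593), and between the zones the list had a median of 0.02 (camera adjusted p = 0.891). NF-kB and CD40 targets were divided against naive cells as well, with 2 higher and 5 lower of 23 (camera adjusted p = 0.662), and Cd40 (-1.54) fell. The medians of this list in the replicate numbers were -0.67 and 0.11. Early response genes had 5 higher and 4 lower of 27 (camera adjusted p = 0.906), among them Ier5 (-2.14) and Nfil3, a regulator of class switching (2.70). Apoptosis regulators had 3 higher and 3 lower (camera adjusted p = 0.192), with the death-promoting genes Pmaip1 and Bid higher by 1.75 and 1.74. Genes of T cell help had 3 higher, such as Tnfsf9 (1.98), and 4 lower (camera adjusted p = 0.199). Plasma cell and secretory genes included Edem1, which clears misfolded proteins, at 2.24 (camera adjusted p = 0.0597), and were called higher by fry (adjusted p = 0.0380). Marginal zone genes had S1pr3 at 4.28 and Cd1d1, which presents lipids, at -2.80 (camera adjusted p = 0.465).

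With all arrays and the deposited scaling, other lists did not pass camera's threshold in either comparison, given here between the zones and then against naive cells. The adjusted p was 0.127 and 0.841 for B cell receptor signalling (0.0364 between the zones after quantile normalization was applied again), 0.856 and 0.0597 for B lineage transcription factors, and 0.518 and 0.824 for heat shock and handling stress genes. Among markers of other cells it was 0.209 and 0.530 for T cells, 0.891 and 0.570 for natural killer cells, 0.891 and 0.406 for macrophages and monocytes, 0.891 and 0.724 for dendritic cells, 0.658 and 0.662 for neutrophils, 0.518 and 0.199 for erythroid cells and platelets, and 0.933 and 0.144 for follicular dendritic and stromal cells. Fry called macrophage and monocyte markers (adjusted p = 0.0252) and erythroid and platelet markers (adjusted p = 0.0294) lower in germinal centre than in naive cells. Of 22 macrophage and monocyte markers 16 had a negative difference, but limma called 3 higher and only 1 lower. It called 0 erythroid and platelet markers in either direction. Sex chromosome markers gave 0.740 and 0.530. Between the zones alone, camera also gave 0.102 for hypermutation genes (median -0.02, mean -0.19), 0.274 for Polycomb genes, 0.731 for immunoglobulin genes and 0.989 for interferon response genes.

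A hypothesis was that the naive level lies nearer the light zone. To keep the arrays apart, the light zone minus dark zone difference of 1 replicate number was correlated across genes with the naive minus germinal centre difference of the other number. Pearson's r was 0.123 and 0.204, above the 0.1 set in advance, and Spearman's rho was 0.0842 and 0.0935, under it, and genes are not independent replicates. Without the genes of the 4 cell cycle lists r was 0.102 and 0.178 over 18103 genes, too near 0.1 to decide whether these genes carry the relation. Leaving out the genes called higher in germinal centre than naive cells as well gave 0.0302 and 0.130 over 16672 genes, but that step filters on a variable of the correlation and decides nothing. Whether the naive level lies nearer the light zone thus stays open.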
